A study of Rattus norvegicus with 48 samples.

How the data were processed

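RNA of 48 rat liver samples was measured on Illumina 1-colour bead arrays, 8 of control liver and 10 in each of the 4 nodule groups, per the labels. Per the file headers, the deposited table without normalisation holds an intensity for each probe and array. Its values are linear bead summaries from which no background had been subtracted. BeadStudio 3.0.19.0 is named for them in the submitters' processing notes. Per the file headers the same table gives a detection p-value for each intensity, the share of negative control beads as bright as the probe. Its steps correspond to 825 control bead types. The deposited value table holds intensities that the authors quantile normalised between arrays on the linear scale without subtracting background, as read from the values. Ranks in each column followed the intensities before normalisation, and the sorted values lay within 2.05% of their mean over arrays. The genome build and the annotation used by the authors are not given in the sources used here.

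Each array was mapped to its label by its column. All 48 columns of the value table matched their own array, and no arrays were identical. Of 22523 probes, 13793 carried a single gene symbol, 8730 carried none and stayed in the tests as unnamed features, and no probe carried several.

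Intensities were corrected for background with normexp from the detection p-values, quantile normalised and put on the log2 scale with an offset of 16, with the function neqc of limma 3.58.1 in R 4.3.3 (data.table version 1.17.8). Probes with a detection p-value under 0.05 on at least 8 arrays were kept, 11723 in number. For a gene with several kept probes the one with the highest mean over all arrays was used, which left 11558 features (8223 named genes and 3335 unnamed probes). Of 156 genes with several kept probes, 20 had probes called in opposite directions in some comparison, of which 1 is named in the report. Probes named for genes followed throughout numbered 1, except for Gstp1 (3) and Alb (2).

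A linear model with a coefficient per group was fitted to all arrays with limma, with moderated variances that follow the mean. Its 7 contrasts were tested, and p-values were adjusted by the Benjamini-Hochberg method over all features of a contrast. A feature was called at an adjusted p under 0.05. Folds of probes not above background on any array of a group were taken from the lowest detected level and are given as lower bounds. Gene lists, 26 in number, were tested with camera of limma, a competitive test of a list against the other features, with the correlation between the genes of a list estimated from the arrays, and adjusted over the lists of a comparison. Members were counted as called over all features and, separately, adjusted over the list alone.

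The lists cover thyroid hormone targets, thyroid hormone receptors, transporters and deiodinases, preneoplastic markers, mature hepatocyte function, cell cycle, glycolysis, pentose phosphate pathway, gluconeogenesis, tricarboxylic acid cycle, respiratory chain and ATP synthase, fatty acid oxidation, lipogenesis, cholesterol synthesis, bile acids, NRF2 targets, mitochondrial biogenesis, pericentral and periportal hepatocytes and acute-phase proteins. The others hold markers of cholangiocytes, stellate cells and fibroblasts, macrophages, endothelium, lymphocytes, neutrophils and red blood cells. Genes named in the report are, per comparison, the 6 called genes with the largest rise and the 6 with the largest fall in log2, leaving out symbols that are only clone identifiers, up to 4 called members with the largest change of each list described and members that go against their list. Not every member that this rule allows is named, and members whose call depended on a single array were left out of the report after this was seen. Genes named wherever measured included Krt19, Gstp1, Ggt1, Afp, Epcam, Sox9, Cd44, Thrsp, Dio1, Me1, Thra, Thrb, Alb, Hnf4a, Cyp7a1, Mki67 and Ccnd1. Among them Ggt1, Sox9 and Mki67 had no probe under these symbols. This rule, the groups, the comparisons, the tests, the lists and all alternatives not marked below as chosen later were fixed before the data were examined.

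The return of nodule changes towards control was measured in 100 random divisions of the KRT-19-positive arrays. A set of 5 arrays defined the features changed against control, and the other 5 were the baseline for T3, so that chance values of the same arrays could not produce a return. Overlaps of comparisons that share a group were set beside groups without change simulated with the residual spread of the arrays, and beside splits of the shared group.

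The procedures were tested on simulated data with the spread of these arrays. Of 50 features changed by 0.5 log2, 50% to 68% were recovered over the 7 comparisons. For a change of 1 log2 the share was 94% to 98%, and for 2 and 3 log2 it was 100.0%. Between 6 and 16 of the unchanged features were called in a comparison. Camera recovered all 26 lists of random genes shifted by 0.5 log2 and gave p under 0.05 for 1.92% of unchanged random lists. The simulated genes varied independently of each other. The values for camera therefore do not show its power or error rate on lists of correlated genes, which was not tested. A simulated return of 60% was estimated as 60.0%.

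The alternatives were quantile normalisation without background correction, normexp with an offset of 50 and without detection p-values, the authors' processed values, no filter and a strict filter (detection p-value under 0.01 on 24 arrays), the mean of all probes of a gene, only the groups compared, array weights, no trend of the variance, a minimum change of 2-fold, camera with a preset correlation of 0.01, the test fry, leaving out each array and, chosen later, the number of detected probes of each array as a covariate, the earlier and later title numbers of each group as a block and leaving out the 4 arrays of T3 4 d on the far side of the largest gap in the first principal component. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Nothing was left out of the arrays given.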

Results

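Gene expression was measured in rat liver with 1-colour bead arrays, on which each probe reports the brightness of labelled RNA bound to it. The 48 arrays fell into 5 groups of samples from male Fischer rats: 8 control livers, 10 preneoplastic nodules that the labels call negative for keratin 19 (KRT-19), 10 KRT-19-positive nodules, and KRT-19-positive nodules after 2 d or 4 d of triiodothyronine (T3), the active thyroid hormone, with 10 samples at each time. Preneoplastic nodules are early lesions of altered hepatocytes, and KRT-19 is a keratin of bile duct and progenitor cells. The labels give neither the T3 dose nor the way the nodules were induced. Between 8380 and 10695 of 22523 probes per array were detected above background, and the raw median intensity ranged from 93 to 198. In control liver, KRT-19-negative and KRT-19-positive nodules arrays with earlier and with later title numbers (1 to 4 against 5 to 8 in control, 1 to 5 against 6 to 10 in nodules) differed by 510, 751 and 225 features, more than in any other division of the group into equal parts, and the fit does not model this. The number of arrays limits the precision. The labels do not say that the samples of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Log2 values are given with the SE of the difference from the fit or with the SD of the arrays, and a difference was called at a limma adjusted p under 0.05.

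**Figure D1:**
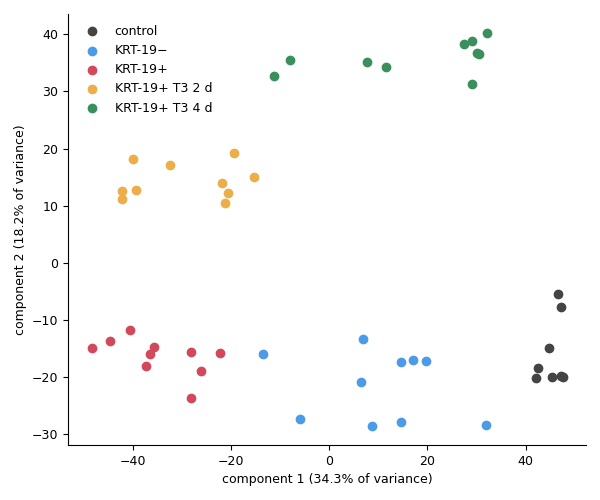
First (horizontal axis) and second (vertical axis) principal component of the normalised log2 values of 11558 features, in arbitrary units, with a point per array coloured by group. The components held 34.3% and 18.2% of the variance, control arrays lay between 42.0 and 47.6 on the first, and arrays after 4 d of T3 lay between 31.3 and 40.2 on the second.

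Krt19, the gene for which the nodule groups are named, followed the labels and its difference between those groups is no finding. Its mean log2 level was 6.51 ± 0.68 (SD, n = 8) in control liver, 8.37 ± 1.54 (SD, n = 10) in KRT-19-negative nodules and 11.82 ± 0.62 (SD, n = 10) in KRT-19-positive nodules. The KRT-19-negative arrays ranged from 6.06 to 10.09 and the KRT-19-positive arrays from 11.03 to 12.73, so both ranges were separate. Krt19 was nevertheless 3.65-fold higher in KRT-19-negative nodules than in control (adjusted p = 0.000439). After 2 d of T3 its mean was 10.25 ± 0.83 (SD, n = 10), and after 4 d it was 8.03 ± 0.44 (SD, n = 10), within the range of the KRT-19-negative nodules.

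**Figure D2:**
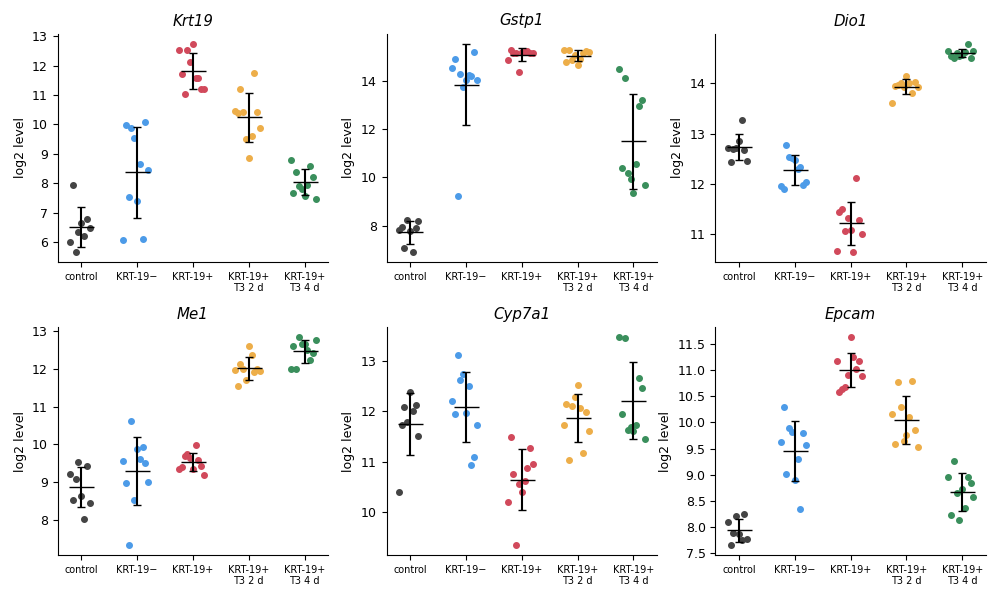
Normalised log2 level (vertical axes) of Krt19, Gstp1, Dio1, Me1, Cyp7a1 and Epcam in the 5 groups (horizontal axes), with a point per array and a bar with whiskers for the mean and SD. Dio1 lay at 14.50 to 14.78 after 4 d of T3, above all control arrays, whereas Gstp1 after 4 d spread from 9.36 to 14.50.

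The first comparison asked how KRT-19-negative nodules differed from control liver (n = 10 and n = 8). The placental glutathione transferase Gstp1, the classical marker of preneoplastic rat hepatocytes, showed the largest difference, at 13.84 ± 1.67 (SD, n = 10) against 7.73 ± 0.47 (SD, n = 8), a 68.8-fold higher level (adjusted p = 6.63e-13). The next largest rises over control were in the glutathione transferase Gsta3 (5.10 ± 0.34), the aldo-keto reductases Akr1b8 (4.55 ± 0.60) and Akr7a3 (4.37 ± 0.31), the conjugate exporter Abcc3 (4.47 ± 0.46) and the glutathione peroxidase Gpx2 (4.01 ± 0.37). The largest falls were in the aldehyde oxidase Aox3 (-3.48 ± 0.46), the insulin receptor substrate Irs3 (-3.29 ± 0.17), the lipoprotein lipase inhibitor Angptl4 (-2.92 ± 0.22), Gimd1 (-2.84), the lipocalin Obp3 (-2.82 ± 0.84) and the liver-intestine cadherin Cdh17 (-2.67).

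Among lists of genes fixed before the data were examined, those of preneoplastic markers and of targets of NRF2, the regulator of the oxidative stress response, held the largest shares of higher members in KRT-19-negative nodules. Each list was tested with camera, a test of a whole list, with the correlation between its genes estimated from the arrays. Of 20 measured preneoplastic markers, 15 were higher, 1 was lower and 4 did not pass (15 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0654). Igf2 went the other way and was not above background on any of these nodule arrays, at a level at least 1.98-fold lower than in control. NRF2 targets were higher for 16, lower for 1 and short of the threshold for 4 of 21 (17 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0654). The heme oxygenase Hmox1 (-0.81) went against the others. Among the fatty acid oxidation genes, 1 was higher, 12 were lower and 14 did not pass of 27 (1 higher and 13 lower adjusted over the list alone, camera adjusted p = 0.315). Among them were the omega-hydroxylase Cyp4a3 (-0.81) and the peroxisomal transporter Abcd3 (-0.60), against the thiolase Acaa2 (0.41). Of 13 measured macrophage markers, 1 was higher, 7 were lower and 5 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.315). The scavenger receptor Marco (-1.96 ± 0.33) and Vsig4 (-0.90) were lower and Cd14 (0.94) was higher. Genes of mature hepatocyte function were higher for 3, lower for 9 and short of the threshold for 26 of 38 (5 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.732).

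Of the genes followed in every comparison, Epcam (1.53 ± 0.19), a surface protein of bile duct and progenitor cells, and the adhesion receptor Cd44 (0.63) were also higher in KRT-19-negative nodules. The thyroid hormone receptor Thra (-0.84) and the deiodinase Dio1 (-0.45), which converts thyroid hormones, were lower. Afp (-0.32), Thrsp (0.01), Me1 (0.43), Thrb (-0.27), Alb (0.19), Hnf4a (0.27), Cyp7a1 (0.34) and Ccnd1 (0.43) did not pass the threshold. Ccnd1 passed when the fit left out KRT-19-negative arrays 1, 3, 4 or 8 (adjusted p = 0.031, 0.0185, 0.0274 and 0.022) or control arrays 5 or 6 (adjusted p = 0.019 and 0.0218). Me1 passed without KRT-19-negative array 3 (adjusted p = 0.00913, difference 0.64). Probes were above background on only some KRT-19-negative arrays for Aox3 (9 of 10), Cd44 (8) and Gimd1 (2), and on only some control arrays for Akr1b8 (4 of 8), Cd44 (2), Gpx2 (5), Gsta3 (2) and Hnf4a (7). Cd44 no longer passed with array weights (adjusted p = 0.0797). Cd44 and Cyp4a3 no longer passed with earlier and later title numbers as a random block (adjusted p = 0.0668 and 0.0523). Alb passed with the number of detected probes as a covariate (adjusted p = 0.0283). Ccnd1 passed with the strict filter and earlier and later title numbers as a fixed block (adjusted p = 0.041 and 0.0418). In all, 2537 of 11558 features differed, 1299 higher and 1238 lower in KRT-19-negative nodules than in control, and 340 of them by at least 2-fold (202 higher, 138 lower, and 130 to 177 in all with other normalisations). For 21 of the 25 differences named here, all 10 arrays lay beyond the mean of the other group (largest adjusted p = 0.018). The number of all differing features was 1687 in the fit to the compared groups only, and also 1687 with earlier and later title numbers as a random block. None of the 26 lists passed camera with an estimated correlation between genes, 3 had an unadjusted p under 0.05, and 13 passed with a preset correlation of 0.01.

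KRT-19-positive nodules were set against control liver in the same way (n = 10 and n = 8), and differed from it more widely. The defensin Defb1 was at least 180.1-fold and the neurofilament subunit Nefl at least 91.1-fold higher, as neither was above background on any control array. The largest rises also included Akr1b8 (7.84 ± 0.60), Gsta3 (6.60 ± 0.34) and the calmodulin-binding protein Pcp4 (6.19 ± 0.51). Gstp1 was 161-fold higher, at 15.07 ± 0.28 (SD, n = 10) against 7.73 ± 0.47 (SD, n = 8), and came within 0.20 log2 of 15.27, the highest value that quantile normalisation left to any probe, so a larger difference would not show. The largest falls were in Obp3 (-5.53 ± 0.84), Aox3 (-4.79 ± 0.46), Angptl4 (-4.54 ± 0.22), the olfactory receptor Olr59 (-4.53), Cdh17 (-4.13) and the vasopressin receptor Avpr1a (-4.10 ± 0.35), which marks pericentral hepatocytes.

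Among the preneoplastic markers, 17 were higher, 2 were lower and 1 did not pass of 20 (the same counts adjusted over the list alone, camera adjusted p = 0.092) in KRT-19-positive nodules. Besides those above, the drug exporter Abcb1b (5.70 ± 0.54), Abcc3 (5.61 ± 0.46) and Epcam (3.07 ± 0.19) were higher, whereas Afp (-1.15 ± 0.15), the fetal albumin homologue, and Igf2 (-1.48) were lower. Of 21 measured NRF2 targets, 19 were higher and 2 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.092). Gpx2 (6.18 ± 0.37) led them. Genes of mature hepatocyte function were higher for 4, lower for 28 and short of the threshold for 6 of 38 (5 higher and 28 lower adjusted over the list alone, camera adjusted p = 0.102). The cytochromes Cyp2c11 (-3.04 ± 0.80) and Cyp1a2 (-2.97 ± 0.38) and the glycine methyltransferase Gnmt (-1.99) were lower. The xenobiotic receptor Nr1i3 (0.78) and Ugt2b (0.68) were higher.

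Among the markers of pericentral hepatocytes, 2 were higher and 12 were lower of 14 (the same counts adjusted over the list alone, camera adjusted p = 0.113) in KRT-19-positive nodules. Slc13a3 (-2.97) was among those lower, and Aldh1a1 (3.74) and Rhbg (3.01) were higher. Of 15 measured markers of periportal hepatocytes, 2 were higher, 9 were lower and 4 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.113). The histidine ammonia-lyase Hal (-2.37) was among them. Pentose phosphate genes were higher for 1, lower for 1 and short of the threshold for 2 of 4 (the same counts adjusted over the list alone, camera adjusted p = 0.738). Their median was -0.03, their mean 0.23, and camera pointed up.

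Lists of metabolic genes were looked at next in KRT-19-positive nodules against control. Among the genes of bile acid synthesis and transport, 2 were higher, 11 were lower and 1 did not pass of 14 (the same counts adjusted over the list alone, camera adjusted p = 0.102). The sterol hydroxylase Cyp8b1 (-3.06 ± 0.34), the acyl-CoA synthetase Slc27a5 (-2.58) and Cyp7a1 (-1.11 ± 0.28), the rate-limiting enzyme of bile acid synthesis, were lower, and Abcc3 and Akr1d1 (0.35) were higher. Of 27 measured fatty acid oxidation genes, 2 were higher, 19 were lower and 6 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.102). Cyp4a3 (-2.55 ± 0.25), Acsl1 (-1.63) and the carnitine palmitoyltransferase Cpt1a (-1.31) were lower and Acaa2 (1.08) and Etfa (0.40) were higher. Lipogenic genes were higher for 1, lower for 11 and short of the threshold for 2 of 14 (1 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.102). The fatty acid elongase Elovl5 (-1.89) and the desaturase Fads2 (-1.59) were lower and the malic enzyme Me1 (0.67) was higher. Among the thyroid hormone receptors, transporters and deiodinases, 9 were lower and 4 did not pass of 13 (10 lower adjusted over the list alone, camera adjusted p = 0.0939). Dio1 (-1.51 ± 0.12), the transporter Slco1b2 (-2.07), Thrb (-0.95 ± 0.15) and Thra (-0.47) were lower. Thra no longer passed without control array 5 (adjusted p = 0.0514). Of 20 measured genes induced by thyroid hormone in liver, 3 were higher, 12 were lower and 5 did not pass (3 higher and 14 lower adjusted over the list alone, camera adjusted p = 0.102). The glucose-6-phosphatase G6pc1 (-3.01 ± 0.27) and Thrsp (-0.65) were lower and Me1, the sterol transporter Abcg5 (1.27) and the uncoupling protein Ucp2 (0.57) were higher.

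Cell cycle genes were higher for 21 and short of the threshold for 10 of 31 (22 higher adjusted over the list alone, camera adjusted p = 0.132) in KRT-19-positive nodules against control. Among them were Cdk1 (1.83 ± 0.30), the ribonucleotide reductase subunit Rrm2 (1.80 ± 0.25) and Ccnd1 (1.08). Among the stellate cell and fibroblast markers, 11 were higher, 1 was lower and 1 did not pass of 13 (the same counts adjusted over the list alone, camera adjusted p = 0.113). The collagens Col1a1 (2.25 ± 0.31) and Col3a1 (2.03) and the metalloproteinase inhibitor Timp1 (1.78) were higher and Des (-0.57) was lower. Smaller shares of the macrophage and endothelial markers differed. Of 13 measured macrophage markers, 4 were higher, 3 were lower and 6 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.874). Their median was 0.17, their mean -0.07, and camera pointed up. Marco (-3.21 ± 0.33) and Vsig4 (-0.81) were lower and Trem2 (1.25) and C1qc (0.73) were higher. Endothelial markers were higher for 1 and short of the threshold for 6 of 7 (the same counts adjusted over the list alone, camera adjusted p = 0.797). Among the cholangiocyte markers, 6 were higher, 2 were lower and 3 did not pass of 11 (the same counts adjusted over the list alone, camera adjusted p = 0.113), Krt19 and Epcam included. Tff3 was not above background on any control array and was at least 2.47-fold higher. Of 5 measured red blood cell markers, 1 was higher and 4 were lower (the same counts adjusted over the list alone, camera adjusted p = 0.113). The globins Hba-a1 (-1.76) and Hbb (-1.97) were lower and Ahsp (1.01) was higher. Neutrophil markers were lower for 1 and short of the threshold for 2 of 3 (none called adjusted over the list alone, camera adjusted p = 0.874). Cd44 (1.73) was higher, and Alb (0.07) and Hnf4a (-0.22) did not pass the threshold. In every group Alb lay 0.31 to 0.64 log2 below the highest value left to any probe, so larger differences may not show. Signal above background was seen on only some KRT-19-positive arrays for Aox3 (9 of 10), Igf2 (1) and Slc13a3 (8), and on only some control arrays for Abcb1b (7 of 8), Ahsp (6), Akr1b8 (4), Cd44 (2), Cdk1 (6), Col1a1 (2), Gpx2 (5), Gsta3 (2), Hnf4a (7), Rrm2 (3) and Trem2 (1). Des, Etfa, Me1 and Ucp2 no longer passed with the number of detected probes as a covariate (adjusted p = 0.148, 0.0809, 0.0754 and 0.77, differences -0.36, 0.25, 0.60 and 0.07). Alb passed with the number of detected probes as a covariate (adjusted p = 0.00055, difference 0.45). In all, 5629 of 11558 features differed, 2868 higher and 2761 lower in KRT-19-positive nodules than in control, and 1348 of them by at least 2-fold (767 higher, 581 lower, and 707 to 841 in all with other normalisations). The 63 differences named here had adjusted p-values up to 0.0187, and for 60 of them all 10 arrays lay beyond the other group's mean. No list passed camera with an estimated correlation, although 10 had an unadjusted p under 0.05 and 17 of 26 passed with the preset one.

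Both kinds of nodule were compared with the same control arrays, so their differences share chance values. In all, 1143 features were higher and 1060 lower in both, and 12 were called in opposite directions. Independent lists of these sizes would share 322 and 296. Unchanged groups simulated against shared controls called only 0.34 and 0.04 features on average and shared 0.01 and 0.01, too few to judge overlaps. With the controls split in 2 separate sets, 732 and 589 features on average were shared. The covariance of the log2 differences across features was 0.277, against 0.0148 in the simulated groups and 0.257 with split controls, where features are not independent replicates.

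Set directly against KRT-19-negative nodules, KRT-19-positive nodules (n = 10 each) had higher levels of Nefl (5.96 ± 0.61, 62.1-fold), Defb1 (4.23 ± 0.69), the platelet-activating factor hydrolase Pla2g7 (4.16 ± 0.33), the protease cathepsin E (Ctse, 3.80 ± 0.36), Abcb1b (3.60 ± 0.51) and, by definition, Krt19 (3.45). The largest falls were in Obp3 (-2.71 ± 0.80), the dehydrogenase Dhrs7l1 (-2.58), the urinary protein gene Mup4l3 (-2.54), the omega-hydroxylase Cyp4a2 (-2.51), Avpr1a (-2.46) and Cyp8b1 (-2.42 ± 0.32). Among the NRF2 targets, 17 were higher and 4 did not pass of 21 (18 higher adjusted over the list alone, camera adjusted p = 0.0701). Among them were Akr1b8 (3.29 ± 0.57), Gpx2 (2.18) and the quinone reductase Nqo1 (1.63). Of 20 measured preneoplastic markers, 16 were higher, 1 was lower and 3 did not pass (17 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0701). Aldh3a1 (2.93 ± 0.32) and Epcam (1.54) were higher and Afp (-0.83) was lower. Genes of mature hepatocyte function were higher for 1, lower for 27 and short of the threshold for 10 of 38 (1 higher and 29 lower adjusted over the list alone, camera adjusted p = 0.0547). Among the bile acid genes, 1 was higher, 11 were lower and 2 did not pass of 14 (2 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.0547). Cyp7a1 (-1.44) and Slc27a5 (-1.77) were lower.

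Of 9 measured gluconeogenic genes, 1 was higher, 7 were lower and 1 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.055) in KRT-19-positive against KRT-19-negative nodules. G6pc1 (-2.09), the serine dehydratase Sds (-1.61) and the carboxykinase Pck1 (-1.34) were lower and Pck2 (0.65) was higher. Genes of thyroid hormone transport and action were lower for 9 and short of the threshold for 4 of 13 (1 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.0547). They included Dio1 (-1.07 ± 0.12) and Thrb (-0.68). Among the cell cycle genes, 15 were higher and 16 did not pass of 31 (17 higher adjusted over the list alone, camera adjusted p = 0.177). Cdk1 (1.07) and Ccnd1 (0.65) were higher. Of 13 measured macrophage markers, 9 were higher, 2 were lower and 2 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.133). Cybb (1.12) and Trem2 (0.98) were higher and Marco (-1.24) and Cd14 (-0.65) lower. Lymphocyte markers were higher for 6 and short of the threshold for 7 of 13 (the same counts adjusted over the list alone, camera adjusted p = 0.225). Among them were Cd3g (0.75) and Ptprc (0.74). Stellate cell and fibroblast markers were higher for 11 and short of the threshold for 2 of 13 (camera adjusted p = 0.0701). Adjusted over the list alone, 12 were higher and 1 lower. Among the acute-phase proteins, 1 was higher, 6 were lower and 8 did not pass of 15 (2 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.225). Cd44 (1.10) was higher and Thrsp (-0.66) lower. Gstp1 (1.23 ± 0.50), Me1 (0.24), Thra (0.37), Alb (-0.12) and Hnf4a (-0.49) did not pass the threshold. In KRT-19-positive nodules Gstp1 lay near the highest value left to any probe, so a larger difference would not show. Without KRT-19-negative array 3 its difference was 0.72 (adjusted p = 0.2). Gstp1 passed without KRT-19-positive array 5 (adjusted p = 0.0491) or KRT-19-negative arrays 1, 2 or 9 (adjusted p = 0.0497, 0.0382 and 0.0309). Hnf4a passed without KRT-19-positive array 8 (adjusted p = 0.0255). Thra passed without KRT-19-positive array 7 (adjusted p = 0.04) or KRT-19-negative arrays 9 or 10 (adjusted p = 0.0373 and 0.0358). Background was exceeded on only some KRT-19-positive arrays for Ptprc (9 of 10), and on only some KRT-19-negative arrays for Abcb1b (9 of 10), Aldh3a1 (3), Cd3g (8), Cd44 (8), Cdk1 (9), Ctse (8), Cybb (6), Defb1 (8), Nefl (6), Pla2g7 (4), Ptprc (7) and Trem2 (4). Cd14, Cd3g, Marco, Ptprc and Trem2 no longer passed with the number of detected probes as a covariate (adjusted p = 0.0697, 0.102, 0.094, 0.422 and 0.114, differences -0.45, 0.50, -0.77, 0.27 and 0.57). Gstp1 passed with quantile normalisation alone, normexp without detection p-values, the authors' processed values, the strict filter, the mean of its probes and only the groups compared (adjusted p = 0.0439, 0.0462, 0.0472, 0.0454, 0.0275 and 0.0478). Hnf4a passed with quantile normalisation alone, the authors' processed values, only the groups compared, array weights and the number of detected probes as a covariate (adjusted p = 0.0481, 0.0476, 0.0239, 0.00473 and 0.0481, differences -0.23, -0.24, -0.49, -0.62 and -0.64). Thra passed with earlier and later title numbers as a fixed block (adjusted p = 0.0427). In all, 3706 of 11558 features differed, 2005 higher and 1701 lower in KRT-19-positive nodules than in KRT-19-negative nodules, and 534 of them by at least 2-fold (317 higher, 217 lower, and 260 to 316 in all with other normalisations). All 10 arrays lay beyond the mean of the other group for 34 of the 36 differences named here, whose largest adjusted p was 0.012. No list passed camera with an estimated correlation, 13 had an unadjusted p under 0.05, and 18 of 26 passed with the preset one.

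The T3 groups addressed what the hormone does to KRT-19-positive nodules. After 2 d of T3 (n = 10 each), the acyl-CoA thioesterase Acot5 rose most (3.51 ± 0.20, 11.4-fold). The mitochondrial glycerol-3-phosphate dehydrogenase Gpd2 (2.93 ± 0.16), the pyruvate dehydrogenase phosphatase Pdp2 (2.79 ± 0.15), Dio1 (2.72 ± 0.12), the zinc finger protein Zfp354a (2.68) and Me1 (2.48 ± 0.22) followed. The largest falls were in Stac3 (-4.59 ± 0.31, above background on 2 of the 10 treated arrays), known from muscle excitation-contraction coupling, Cyp2c11 (-2.63 ± 0.75), the aldehyde dehydrogenase Aldh3a1 (-2.37 ± 0.32), Sdr16c6 (-2.21), the RNA-binding protein Celf5 (-2.09) and the cytochrome Cyp2b15 (-1.88). Of 20 measured genes induced by thyroid hormone in liver, 14 were higher and 6 did not pass (16 higher adjusted over the list alone, camera adjusted p = 0.000163), the 1 list that passed at this time. Besides Dio1, Me1 and Gpd2, Abcg5 (2.31 ± 0.24) and Thrsp (0.53 ± 0.14), a lipogenic regulator, rose.

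Cell cycle genes were higher for 21 and short of the threshold for 10 of 31 (25 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0956) after 2 d. Among them were Rrm2 (1.45 ± 0.24), the replication helicase subunit Mcm6 (1.19 ± 0.13), Cdc20 (1.13) and Ccnd1 (0.43). Ccnd1 no longer passed when the fit left out KRT-19-positive arrays 4 or 7 (adjusted p = 0.053 and 0.0529) or T3 2 d arrays 2 or 5 (adjusted p = 0.0551 and 0.0561). Among the fatty acid oxidation genes, 15 were higher, 2 were lower and 10 did not pass of 27 (16 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0956). Acot1 (2.24 ± 0.22), Cpt1a (1.50 ± 0.14) and Abcd3 (1.37) rose, and Etfa (-0.49) fell. Of 54 measured respiratory chain and ATP synthase subunits, 26 were higher, 1 was lower and 27 did not pass (27 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.199). Cytochrome c (Cycs, 0.90) and Uqcrfs1 (0.62) were higher and Atp5mc2 (-0.43) was lower. Cholesterol synthesis genes were higher for 9, lower for 1 and short of the threshold for 3 of 13 (the same counts adjusted over the list alone, camera adjusted p = 0.237). Fdps (0.83) was higher and Ebp (-0.39) was lower.

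Fewer nodule markers differed after 2 d than after 4 d. Among the preneoplastic markers, 7 were lower and 13 did not pass of 20 (the same counts adjusted over the list alone, camera adjusted p = 0.429). Krt19 (-1.58 ± 0.38), Epcam (-0.95), Prom1 (-0.91) and Cd44 (-0.81) were lower, whereas Gstp1 (-0.04 ± 0.50) stayed at 15.03 ± 0.23 (SD, n = 10), again close to the highest value left to any probe. Of 21 measured NRF2 targets, 3 were higher, 5 were lower and 13 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.842). The thioredoxin reductase Txnrd1 (-0.76) fell, and Me1 and Hmox1 (0.46) rose. Genes of mature hepatocyte function were higher for 5, lower for 11 and short of the threshold for 22 of 38 (7 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.762). Cyp3a18 (-1.75) and Hnf4a (-0.83 ± 0.21), a master regulator of hepatocyte genes, fell, and Nr1i2 (0.51), Slc10a1 (0.49), Cyp4a1 (0.44) and Arg1 (0.55) rose. Cyp7a1 (1.22 ± 0.27) and Thrb (0.56) rose, Thra (-0.53) fell, and Afp (0.14) and Alb (0.26) did not pass the threshold. Alb passed when the fit left out KRT-19-positive arrays 7, 9 or 10 (adjusted p = 0.028, 0.0342 and 0.0362) or T3 2 d array 2 (adjusted p = 0.0431). Probes were above background on only some T3 2 d arrays for Aldh3a1 (5 of 10), Cd44 (9), Celf5 (2), Hnf4a (7), Prom1 (5), Sdr16c6 (3) and Stac3 (2), and on only some KRT-19-positive arrays for Acot1 (1 of 10) and Acot5 (9). Ccnd1 and Hmox1 no longer passed with earlier and later title numbers as a random block (adjusted p = 0.0872 and 0.0612). Thra and Txnrd1 no longer passed with the number of detected probes as a covariate (adjusted p = 0.119 and 0.0661, differences -0.35 and -0.50). Alb passed with array weights and earlier and later title numbers as a fixed block (adjusted p = 0.000161 and 0.00687, differences 0.45 and 0.26). In all, 3620 of 11558 features differed, 1825 higher and 1795 lower in T3-treated nodules than in untreated KRT-19-positive nodules, and 267 of them by at least 2-fold (119 higher, 148 lower, and 97 to 135 in all with other normalisations). For 38 of the 42 differences named here, all 10 arrays lay beyond the mean of the other group (largest adjusted p = 0.0273). With the preset correlation 13 of 26 lists passed.

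After 4 d of T3 (n = 10 each) the response was broader. Acot5 (4.86 ± 0.20, 29.1-fold), Mmd2 (4.60 ± 0.27), the ubiquitin ligase Trim36 (4.14 ± 0.27), Zfp354a (3.93), Pdp2 (3.81) and the mitochondrial carrier Slc25a30 (3.56) rose most against untreated KRT-19-positive nodules. Defb1 (-6.24 ± 0.69, 75.4-fold lower), Nefl (-5.36 ± 0.61), Pla2g7 (-4.75 ± 0.33), Stac3 (-4.74, above background on 1 of 10 treated arrays), Akr1b8 (-4.11 ± 0.57) and Ctse (-3.97) fell most. Among the genes induced by thyroid hormone in liver, 17 were higher and 3 did not pass of 20 (17 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000697). They were led by Dio1 (3.38 ± 0.12), Gpd2 (3.37 ± 0.16), G6pc1 (3.08 ± 0.25) and Me1 (2.92 ± 0.22), with Thrsp (1.12) and Cyp7a1 (1.56 ± 0.27) also higher.

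Of the lists for mitochondria, 4 passed after 4 d. In the fit to the compared groups only, and with the strict filter, none of them did (respiratory chain adjusted p = 0.163 and 0.103, tricarboxylic acid cycle 0.163 and 0.103, fatty acid oxidation 0.163 and 0.103, mitochondrial biogenesis 0.163 and 0.178). Of 54 measured respiratory chain and ATP synthase subunits, 45 were higher and 9 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.03). They were led by Uqcrfs1 (1.44 ± 0.08) and Cycs (1.37 ± 0.07). Tricarboxylic acid cycle genes were higher for 13, lower for 2 and short of the threshold for 2 of 17 (the same counts adjusted over the list alone, camera adjusted p = 0.03). The pyruvate dehydrogenase subunits Pdhb (2.08 ± 0.10) and Dlat (1.50) and the succinyl-CoA synthetase Sucla2 (1.46) rose, and Dlst (-0.21) fell. Among the fatty acid oxidation genes, 20 were higher, 1 was lower and 6 did not pass of 27 (the same counts adjusted over the list alone, camera adjusted p = 0.03). Cpt1a (2.56 ± 0.14) and Cyp4a3 (2.46 ± 0.23) rose and Acaa2 (-0.66) fell. Cpt1a and Cycs also belong to the thyroid hormone targets, so these lists are not independent of that one. Of 19 measured mitochondrial biogenesis genes, 9 were higher and 10 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.03). Tfb2m (0.69) was among them. Their coactivator Ppargc1a was not above background on any untreated array and was at least 1.62-fold higher. Lipogenic genes were higher for 12 and short of the threshold for 2 of 14 (the same counts adjusted over the list alone, camera adjusted p = 0.0532). Among them were Elovl5 (2.95 ± 0.33) and the acetyl-CoA carboxylase Acaca (2.28).

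**Figure D3:**
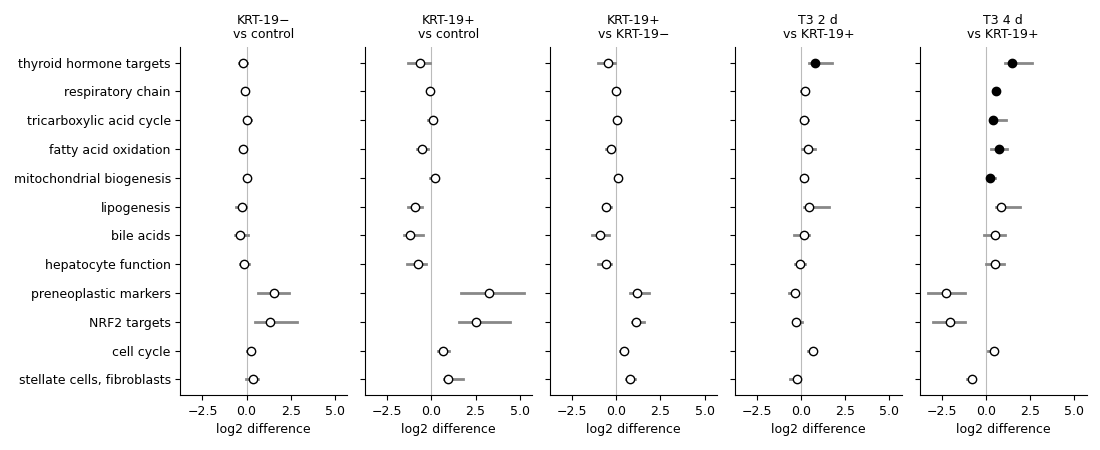
Median log2 difference of the measured members of 12 gene lists (rows) in 5 comparisons (panels), with horizontal bars for the quartiles of the members and filled points where camera with an estimated correlation gave an adjusted p under 0.05. After 4 d of T3, subunits of the respiratory chain had a median of 0.58 and preneoplastic markers a median of -2.28.

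Most nodule markers were lower after the same 4 d. Among the preneoplastic markers, 1 was higher, 16 were lower and 3 did not pass of 20 (the same counts adjusted over the list alone, camera adjusted p = 0.134). Krt19 (-3.80 ± 0.38), Gstp1 (-3.58 ± 0.50), Abcc3 (-3.55 ± 0.44) and Epcam (-2.33) were lower and Afp (0.72) was higher. Arrays 1, 3, 8 and 9 after 4 d stood apart, with Gstp1 at 12.95 to 14.50 and a first principal component of -11.2 to 11.6, against 9.36 to 10.56 and 27.4 to 32.1 on the other 6. Gstp1 lay 1.37 log2 below its untreated mean on the former and 5.05 on the latter, and that mean was near the highest value left to any probe. Of 21 measured NRF2 targets, 1 was higher, 18 were lower and 2 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.15). Gpx2 (-3.51 ± 0.34) was lower and Me1 was higher. Genes of mature hepatocyte function were higher for 20, lower for 3 and short of the threshold for 15 of 38 (the same counts adjusted over the list alone, camera adjusted p = 0.197). Cyp1a2 (2.29 ± 0.36) and the transcription factors Cebpa (2.17 ± 0.24) and Foxa3 (2.06) rose, and Nr1i3 (-0.90), Cyp3a18 (-0.91) and Ugt2b (-0.51) fell. Among the cell cycle genes, 19 were higher, 1 was lower and 11 did not pass of 31 (the same counts adjusted over the list alone, camera adjusted p = 0.475). Rrm2 (1.61 ± 0.24) and Bub1 (1.44) were higher, Cdk4 (-0.87) was lower and Ccnd1 (-0.01) fell short of the threshold. Of 13 measured stellate cell and fibroblast markers, 1 was higher, 10 were lower and 2 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.197). Col1a1 (-2.04 ± 0.30) and Timp1 (-1.75) were lower and Des (0.58) was higher. Cd44 (-1.50) fell and Thrb (0.78) rose, while Thra (-0.12), Alb (-0.05) and Hnf4a (0.14) did not pass the threshold. Signal above background was seen on only some T3 4 d arrays for Cd44 (4 of 10), Col1a1 (4), Defb1 (4), Nefl (4), Pla2g7 (4), Ppargc1a (9) and Stac3 (1), and on only some KRT-19-positive arrays for Acaca (4 of 10), Acot5 (9), Bub1 (7), Mmd2 (3), Slc25a30 (8) and Trim36 (7). Alb passed with the number of detected probes as a covariate (adjusted p = 0.0214, difference -0.24). Without the 4 arrays that stood apart, Cyp3a18 and Dlst no longer passed (adjusted p = 0.21 and 0.0537, differences -0.35 and -0.20), and the difference of Cyp7a1 was 1.03. The preneoplastic, NRF2 and lipogenic lists then passed (adjusted p = 0.0323, 0.0453 and 0.0453). The arrays left out lay furthest from control on the first component, a choice that favours passes of nodule lists. In all, 6205 of 11558 features differed, 3130 higher and 3075 lower in T3-treated nodules than in untreated KRT-19-positive nodules, and 1357 of them by at least 2-fold (619 higher, 738 lower, and 634 to 776 in all with other normalisations). The 51 differences named here had adjusted p-values up to 0.0135, and for 50 of them all 10 arrays lay beyond the other group's mean. With the preset correlation 17 of 26 lists passed.

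Both times share the untreated arrays. In all, 1170 features rose and 1200 fell at both, and 240 changed in opposite directions. Independent lists of these sizes would share 494 and 478. Unchanged groups simulated against the shared arrays called on average 0.64 and 0.06 features and shared 0, again too few. With the untreated arrays split in 2 sets 786 and 744 were shared. The covariance across features was 0.171, against 0.0112 in the simulated groups and 0.163 with split arrays.

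Between the 2nd and the 4th day (n = 10 each) the difference was tested directly. Mmd2 (3.86 ± 0.27), Cyp3a23-3a1 (3.16 ± 0.32), Aox3 (2.88 ± 0.44), Slc13a3 (2.82), Olr59 (2.80) and Obp3 (2.54 ± 0.80) rose most. Defb1 (-5.11 ± 0.69), Nefl (-4.58 ± 0.61), Akr1b8 (-3.88 ± 0.57), Pcp4 (-3.73) and Tceal9 (-3.63) fell most. Gstp1 (-3.54 ± 0.50) fell from a level within 0.24 log2 of the highest value left to any probe, so a larger fall would not show. NRF2 targets were lower for 20 and short of the threshold for 1 of 21 (1 higher and 20 lower adjusted over the list alone, camera adjusted p = 0.108) between these days. They included Gpx2 (-2.92) and Abcc3 (-3.13). Among the preneoplastic markers, 2 were higher, 15 were lower and 3 did not pass of 20 (the same counts adjusted over the list alone, camera adjusted p = 0.191). Krt19 (-2.22), Nqo1 (-2.88) and Epcam (-1.39) were lower and Prom1 (1.01) and Afp (0.58) were higher. Of 38 measured genes of mature hepatocyte function, 24 were higher, 3 were lower and 11 did not pass (25 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.108). Foxa2 (1.91 ± 0.23), Cebpa (1.67) and Hnf4a (0.97 ± 0.21) rose, and Nr1i3 (-0.49), Ugt2b (-0.34) and Alb (-0.31) fell. Respiratory chain and ATP synthase subunits were higher for 41, lower for 2 and short of the threshold for 11 of 54 (43 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.108). Cox6c (0.90) was higher and Ndufs5 (-0.45) was lower. Among the cell cycle genes, 1 was higher, 11 were lower and 19 did not pass of 31 (1 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.535). Mcm3 (-0.93), Tyms (-0.79) and Ccnd1 (-0.44) fell and Bub1 (1.10) rose. Dio1 (0.66), Thrsp (0.60) and Thra (0.41) rose, Cd44 (-0.69) fell, and Me1 (0.44), Thrb (0.22) and Cyp7a1 (0.34) did not pass the threshold. Thra no longer passed when the fit left out T3 2 d arrays 3 or 6 (adjusted p = 0.0945 and 0.0975) or T3 4 d arrays 1, 5 or 6 (adjusted p = 0.0662, 0.062 and 0.0659). The call of Alb rested on the probe chosen, as its probes were called in opposite directions and their mean gave a difference of -0.03 (adjusted p = 0.777). Background was exceeded on only some T3 4 d arrays for Cd44 (4 of 10), Defb1 (4), Mcm3 (4), Nefl (4) and Obp3 (9), and on only some T3 2 d arrays for Aox3 (5 of 10), Bub1 (7), Cd44 (9), Hnf4a (7), Mmd2 (7), Olr59 (5), Prom1 (5) and Slc13a3 (9). Ccnd1 and Thra no longer passed with earlier and later title numbers as a random block (adjusted p = 0.0538 and 0.0852). Thra no longer passed with no filter or with the number of detected probes as a covariate (adjusted p = 0.0558 and 0.0519). Me1 passed with quantile normalisation alone, the authors' processed values, only the groups compared and array weights (adjusted p = 0.0435, 0.0466, 0.00388 and 0.0137). Without the 4 arrays of T3 4 d that stood apart, Alb and Thra no longer passed (adjusted p = 0.0907 and 0.0834), Me1 passed (adjusted p = 0.0333), and the differences of Ccnd1 and Obp3 were -0.70 and 4.27. The preneoplastic and NRF2 lists and the 4 for mitochondria named above passed in that fit (adjusted p = 0.0488 each). That choice again favours nodule lists. In all, 5137 of 11558 features differed, 2587 higher and 2550 lower in nodules after 4 d than in nodules after 2 d, and 780 of them by at least 2-fold (369 higher, 411 lower, and 334 to 418 in all with other normalisations). All 10 arrays lay beyond the mean of the other group for 30 of the 35 differences named here, whose largest adjusted p was 0.0335. No list passed camera with an estimated correlation, 7 had an unadjusted p under 0.05, and 12 of 26 passed with the preset one.

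Nodules after 4 d of T3 were finally set against control liver (n = 10 and n = 8). Gsta3 (5.32 ± 0.34), Acot5 (4.39 ± 0.21), the ornithine decarboxylase Odc1 (4.38 ± 0.30), Ugt1a6 (3.84 ± 0.37), Gstp1 (3.75 ± 0.53) and Akr1b8 (3.73 ± 0.60) were highest against control. Stac3 (-8.08 ± 0.33, above background on 1 of 10 treated arrays), Dhrs7l1 (-3.98), Cyp2c11 (-3.95 ± 0.80), Irs3 (-3.87), the leukotriene synthase Ltc4s (-3.75, likewise on 1) and Cyp3a9 (-3.55) were lowest against control. Of 17 measured tricarboxylic acid cycle genes, 14 were higher and 3 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.00201). Among them were Pdhb (1.80 ± 0.11) and Cs (1.19). Respiratory chain and ATP synthase subunits were higher for 44 and short of the threshold for 10 of 54 (45 higher adjusted over the list alone, camera adjusted p = 0.026). They were led by Cycs (1.31). Among the mitochondrial biogenesis genes, 14 were higher, 1 was lower and 4 did not pass of 19 (the same counts adjusted over the list alone, camera adjusted p = 0.000306). Mrpl13 (1.06) was higher and Polg (-0.77) was lower. Of 20 measured genes induced by thyroid hormone in liver, 12 were higher, 3 were lower and 5 did not pass (13 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0251). Abcg5 (3.72 ± 0.25), Me1 (3.59 ± 0.23) and Dio1 (1.87 ± 0.12) were higher, and Angptl4 (-1.79), Acly (-0.54) and Scarb1 (-0.43) lower. Cell cycle genes were higher for 25 and short of the threshold for 6 of 31 (27 higher adjusted over the list alone, camera adjusted p = 0.038). Rrm2 (3.42 ± 0.25), Cdk1 (2.64 ± 0.30) and Ccnd1 (1.06) were higher. Among the glycolytic genes, 7 were higher, 1 was lower and 6 did not pass of 14 (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.026). The aldolase Aldoa (1.16) was higher. With the strict filter the lists of cell cycle, respiratory chain, glycolysis and thyroid hormone targets did not pass (adjusted p = 0.102, 0.0629, 0.0629 and 0.0629). Nor did cell cycle with quantile normalisation alone or the authors' processed values (adjusted p = 0.0539 and 0.0541), or the respiratory chain in the fit to the compared groups only (adjusted p = 0.0779).

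Of 20 measured preneoplastic markers, 13 were higher, 2 were lower and 5 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.458) after 4 d of T3 against control. Krt19 (1.52 ± 0.40) and Epcam (0.74) were higher and Igf2 (-1.29) and Afp (-0.43) lower. Bile acid genes were higher for 2, lower for 8 and short of the threshold for 4 of 14 (the same counts adjusted over the list alone, camera adjusted p = 0.448). Cyp8b1 (-2.12) was lower, Abcc3 (2.06) and Cyp27a1 (0.39) were higher, and Cyp7a1 (0.46) did not pass the threshold. Thrsp (0.47) was higher and Thra (-0.59) lower, and Cd44 (0.22), Thrb (-0.17), Alb (0.03) and Hnf4a (-0.08) did not pass the threshold. Probes were above background on only some T3 4 d arrays for Cd44 (4 of 10), Cyp2c11 (8), Dhrs7l1 (9), Igf2 (1), Irs3 (9), Ltc4s (1) and Stac3 (1), and on only some control arrays for Acot5 (6 of 8), Akr1b8 (4), Cd44 (2), Cdk1 (6), Gsta3 (2), Hnf4a (7), Odc1 (2), Rrm2 (3) and Ugt1a6 (4). Afp no longer passed with array weights (adjusted p = 0.0761). Afp and Scarb1 no longer passed with the number of detected probes as a covariate (adjusted p = 0.0509 and 0.0627, differences -0.37 and -0.28). Without the 4 arrays of T3 4 d that stood apart, Abcc3, Acly, Afp and Epcam no longer passed (adjusted p = 0.12, 0.0708, 0.252 and 0.0505, differences 0.63, -0.47, -0.24 and 0.51), and the differences of Akr1b8, Cyp2c11 and Gstp1 were 2.16, -2.14 and 2.28. In all, 4857 of 11558 features differed, 2505 higher and 2352 lower in nodules after 4 d of T3 than in control, and 845 of them by at least 2-fold (490 higher, 355 lower, and 354 to 444 in all with other normalisations). For 36 of the 36 differences named here, all 10 arrays lay beyond the mean of the other group (largest adjusted p = 0.0154). With the preset correlation 9 of 26 lists passed.

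How far T3 moved the changes of KRT-19-positive nodules back towards control was measured with separate arrays for the change and for its baseline. In 100 random draws, 1 set of 5 KRT-19-positive arrays defined the features changed at least 2-fold against control, 1378 on average, and the other 5 served as the baseline for T3. After 2 d, 64.4% of these features moved the opposite way (range over draws 56.2 to 74.3%) and 23.4% were called doing so, against 7.79% called as moving further from control. After 4 d, 89.6% moved back (86.8 to 92.2%), 74.9% were called, and 3.45% were called as moving further. The median feature had returned by 11.2% of its change after 2 d and by 63.1% after 4 d (52.7 to 76.2%). Features that had been higher in nodules returned by 15.4% after 2 d and 67% after 4 d, and those that had been lower by 4.09% and 55.9%. With unchanged arrays simulated in place of the T3 groups, 49.9% moved the opposite way, which follows from their construction and is no independent test. The draws share arrays, so their range is no confidence interval.

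**Figure D4:**
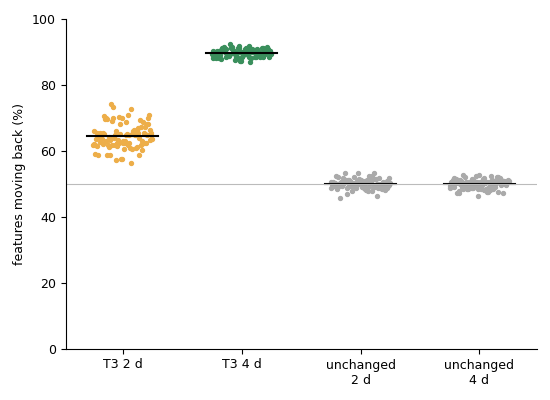
Share of features changed at least 2-fold in KRT-19-positive nodules that moved back towards control, in percent (vertical axis), for observed and simulated unchanged T3 groups after 2 d and 4 d (horizontal axis), with a point for each of 100 random draws and a bar for their mean. The observed means were 64.4% after 2 d and 89.6% after 4 d, against about 50% by construction for unchanged groups.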

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

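The tests of non-nodular liver and of a single probe below were chosen after the result was seen.

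Each gene named in the report, the number of detected probes and the raw median were looked at in all 5 groups, 710 sets of values, for an array whose gap to its nearest neighbour took an unusually large part of the range of its group. Chance marks about 1 in 20 such sets, and 46 were marked here (6.48%). Values are normalised log2 levels unless stated. On KRT-19-negative array 3, Gstp1 (9.25), Gsta3 (6.80), Pcp4 (5.06), Abcc3 (7.39), Akr7a3 (10.31), Aldh1a1 (11.90), Txnrd1 (8.14) and Ugt2b (13.03) were the lowest of the group and Cyp1a2 (12.75) and Cyp27a1 (13.44) were the highest of the group. On control array 2, Foxa3 (8.62) and Col3a1 (6.89) were lowest and Nefl (4.88), Slc27a5 (14.37) and Dlst (9.75) were highest. On KRT-19-negative array 2, Thrsp (13.59) was lowest and Timp1 (9.86) and Cdc20 (8.03) were highest. On T3 4 d array 3, Polg (8.12) was lowest and Celf5 (6.21) and Akr1d1 (12.01) were highest. On KRT-19-positive array 8, Mcm6 (7.43) was lowest and Hnf4a (7.31) highest. On T3 2 d array 2, Ndufs5 (12.63) was lowest and number of detected probes (10259) highest. Single marks on control arrays were Hnf4a of array 3 (5.00, lowest), Cyp7a1 of array 1 (10.40, lowest), Gpx2 of array 5 (7.03, highest), Mcm3 of array 6 (5.53, highest) and C1qc of array 8 (11.90, highest). Single marks on KRT-19-negative arrays were Pla2g7 of array 9 (8.36, highest), Cdh17 of array 1 (6.06, lowest), Hba-a1 of array 4 (11.77, lowest) and Cs of array 5 (5.97, lowest). Single marks on KRT-19-positive arrays were Gstp1 of array 5 (14.35, lowest), Acot1 of array 1 (5.36, highest), Vsig4 of array 7 (9.68, highest) and Ptprc of array 9 (5.11, lowest). Single marks on T3 2 d arrays were Ltc4s of array 8 (6.51, highest), Gimd1 of array 4 (5.62, highest), Igf2 of array 5 (5.48, highest) and Acaa2 of array 6 (12.86, lowest). Single marks on T3 4 d arrays were Ltc4s of array 6 (5.45, highest), Sds of array 1 (11.07, lowest), Igf2 of array 10 (6.18, highest) and Pck2 of array 5 (6.06, lowest).

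Effects that differed between groups were also looked for. 12 features were called in opposite directions in KRT-19-negative and in KRT-19-positive nodules against control, and for each of them the direct comparison of both kinds of nodule was also called. Chosen after their values were seen, Hebp2 (-0.88 and 0.76), Plat (-0.62 and 0.58) and the reelin gene Reln (-0.58 and 0.46) were lower in the first and higher in the second, and Ugt2b1 (0.72 and -0.84) and the glutamine transporter Slc38a3 (0.44 and -0.75) the reverse. 240 features were called in opposite directions after 2 d and after 4 d of T3, with Olr59 (-1.44 and 1.37), also chosen after its values were seen, furthest apart.

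KRT-19-negative array 3 gathered 10 of these marks, more than any other array, and its Gstp1 level of 9.25 compares with 13.72 to 15.18 on the other 9 arrays of the group. A fault of the Gstp1 probe is argued against by a separate Gstp1 probe, which lay 4.65 log2 below the lowest of the other arrays. Of 52 features at least 4-fold higher in the other 9 arrays than in control, the median feature kept 6.91% of its excess on this array, against 57.4% to 186% on each of the others, where the features were chosen anew without that array. A candidate explanation is therefore a sample mostly of non-nodular liver. A mislabelled control and a nodule with a weak nodule profile stay open and were not tested.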

How the results depend on the processing

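The covariate, the block of earlier and later title numbers and leaving out 4 arrays of T3 4 d were chosen after seeing the data. The other alternatives came before.

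All 7 comparisons kept their counts within 1.5 times of the value reported under other background corrections, the authors' processed values, both other filters, the mean of all probes of a gene, array weights, no trend of the variance and the covariate. Asking also for a 2-fold change left 340, 1348, 534, 267, 1357, 780 and 845 features, in the order of the Results, fewer by construction. These numbers depended on the normalisation. In the same order they were 134, 714, 266, 100, 652, 343 and 367 with the authors' processed values, 130, 707, 260, 97, 634, 334 and 354 with quantile normalisation alone and 177, 841, 316, 135, 776, 418 and 444 with normexp, an offset of 50 and no detection p-values, and the cause was not tested. Fitted with the arrays of the compared groups only, KRT-19-negative nodules against control had 1687 called features instead of 2537. The same fit gave more features than reported after 2 d of T3 (4288), after 4 d (6653) and for 4 d against 2 d (5576). The cause of these shifts was not tested. Leaving out each array in turn gave, in the order of the 2-fold numbers, 2239 to 2622, 5390 to 5629 and 3378 to 3963 features. For T3 it gave 3355 to 3723, 6004 to 6185, 4859 to 5222 and 4578 to 4855. Over the other alternatives without a block the widest range was 3072 (covariate) to 5262 features (array weights), after 2 d of T3. The number of detected probes follows the groups in part, so its covariate can also remove part of their difference.

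Gene lists depended most on the test. Of 182 tests 12 passed with an estimated correlation, against 99 with a preset correlation of 0.01 and 139 with fry, which tests each list without regard to the other genes. The number was 20 with normexp and an offset of 50, 61 without a filter on dim probes and 4 with the strict filter, and the cause was not tested. None of the 12 lists lost its call when an array was left out, and the highest adjusted p was then 0.0468 (cell cycle, 4 d of T3 against control). The thyroid hormone targets after 2 d and 4 d of T3 against untreated nodules passed under every alternative run (adjusted p up to 0.0217 and 0.0223). After 4 d, the strict filter and the fit to the compared groups only each ended all 4 calls for mitochondria (highest adjusted p 0.178). Against control after 4 d, the highest were 0.102 for cell cycle, 0.0779 for the respiratory chain, and 0.0629 for glycolysis and for thyroid hormone targets.

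Of the genes named in the report, leaving out an array kept 6053 results on their side of the threshold, ended 10 calls and added 19. The other alternatives kept 3758, ended 18 and added 20, with no call reversed, and most calls ended with the covariate. Of 288 called log2 differences of named genes, 79 were over 1.5 times smaller with quantile normalisation alone, 76 with the authors' processed values and 46 with normexp and an offset of 50, and none was larger by as much. List members whose call depended on a single array had been left out of the report after this was seen, so these numbers favour stable genes. The return towards control after 4 d of T3 was 89.6% of features, 91.4% with the authors' processed values and 91.4% with quantile normalisation alone. It was 91.6% without arrays 1, 3, 8 and 9 of T3 4 d. Leaving these arrays out gave 5981 features after 4 d, 4917 for 4 d against 2 d and 4050 for 4 d against control, and for named genes it ended 8 calls and added 1. The return was 81.7% when features changed by less than 2-fold were included, and the cause was not tested. After 2 d it stayed within the spread of the draws with the authors' processed values, with quantile normalisation alone and with these features included.

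The replicate numbers of the titles were tried as a block although nothing says that they pair samples. Of 92 pairs of arrays with the same number, 19 correlated above 0.1 after removal of the group means, and 13 samples matched their own number best. The correlation within a block was estimated as -0.0265. As a fixed block it gave 2282 features for KRT-19-negative nodules against control and 6122 after 4 d of T3, and as a random block 2485 and 6141. Arrays with earlier and with later numbers differed by 510 features in control liver, 751 in KRT-19-negative and 225 in KRT-19-positive nodules. Any other division gave at most 321, 536 and 16 (35 divisions in control liver and 126 in each kind of nodule). After 2 d and 4 d of T3 they differed by 1 and 0 features. What separates them is not in the labels. With earlier and later numbers as a random block (correlation 0.0921) the comparisons had 1687, 4892, 2805, 2552, 5290, 4189 and 4018 features, in the order of the 2-fold numbers, all called before in the same direction, and as a fixed block 2773 to 6408. For named genes these blocks ended 6 calls, all under the random one, and added 3, all under the fixed one. A block by slide was not run, since the files give no slide.

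Signal over background limits what the arrays resolve. 52.0% of the probes passed the filter, and where a group lay below background, as for Igf2, Defb1, Nefl, Tff3 and Ppargc1a, the fold is only a lower bound. Gstp1 reached the upper end of the scale in KRT-19-positive nodules, untreated and after 2 d of T3. Alb lay near it in every group.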

Other observations

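The tests of tissue mixture, of detected probes, of the share of hepatocytes and of sex-dependent genes were chosen only after the results were seen, and that of random splits before. The genes singled out below, and the lists of sex-dependent genes, were chosen after their values were seen.

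Nodule genes differed widely in how much of their excess over control they kept after 4 d of T3. Of 76 features at least 8-fold higher in KRT-19-positive nodules than in control, the median feature kept 12.3% of the excess (quartiles 6.18% and 22.0%). Aldh3a1 kept 0.0662 ± 3.92% (bootstrap SE of the distance from that median), Pla2g7 0.350 ± 3.91%, Defb1 3.09 ± 2.76% and Krt19 4.44 ± 3.50%. Gsta3 kept 49 ± 7.39%, the retinal dehydrogenase Aldh1a1 59.3 ± 4.03%, Myc 37.6 ± 4.48%, and Odc1, the ornithine decarboxylase that is a textbook target of Myc, 143 ± 9.43%.

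Liver genes that differ between the sexes in rats also differed in KRT-19-positive nodules of these male animals. All 8 measured male-biased genes were lower than in control (camera p = 0.089, not adjusted, so the list as a whole did not pass), among them Cyp2c11 (-3.04 ± 0.80) and Cyp4a2 (-3.32 ± 0.36). The female-specific Cyp2c12 was higher (4.05 ± 0.48) and still so after 4 d of T3 (3.30 ± 0.48). After 2 d of T3, 4 of the 8 male-biased genes were lower than in untreated nodules and none was higher (median -0.85). After 4 d, 3 were higher and 1 lower (median 0.39), and 7 were still lower than in control, although 7 had risen since the 2nd day (median 1.41). Of the 6 female-biased genes, 2 were lower after 2 d and 3 higher after 4 d than in untreated nodules, and 4 rose in between (median 1.47). Female-biased genes went both ways in KRT-19-positive nodules, with a median difference from control of -0.21, with 1 of 6 higher and 3 lower. Cyp3a9 (-3.86 ± 0.37) and Cyp2c7 (-2.15 ± 0.33) were among the lower ones, and whether the pattern shifts towards the female one stays open.

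The lower level of nodule markers after 4 d of T3 may come from samples that hold more non-nodular liver, and this stays open. Nodule genes kept unequal parts of their excess, as 67.1% of the 76 features differed from the median by more than 2 bootstrap SE, 26 below and 25 above it. This would argue against admixture only if non-nodular liver on T3 had the profile of untreated control liver, which no group measures. Across the 10 arrays, Gstp1 was lower where the first principal component lay nearer to control (Spearman correlation -0.939), which admixture would also give, as would a response that differs between nodules. A difference in the number of detected probes is argued against as the whole cause, as the fall of the preneoplastic list kept 89.9% of its size with that number as a covariate.

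Collagen and other fibroblast genes were higher in KRT-19-positive nodules than in control, which may reflect a lower share of hepatocytes, with markers of all other cell types rising alike. The mean level of the fibroblast list rose from 8.09 ± 0.18 (SD) to 9.20 ± 0.26 (SD), and by 0.98 log2 more than that of the endothelial list, which went from 7.46 ± 0.16 (SD) to 7.58 ± 0.12 (SD). The macrophage list went from 9.33 ± 0.18 (SD) to 9.27 ± 0.21 (SD). Exact permutation tests of both differences gave p = 2.29e-05, the smallest they can give (n = 10 and n = 8). The tables thus argue against a lower share of hepatocytes alone, while more or more active fibroblasts in the nodules stay open.

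Random splits of the arrays of each comparison into groups of the same sizes, 100 with the real one, asked whether chance could give as many features. In each comparison only 1 of them, the real one, reached its count. That count was 2537 against at most 750 in other splits for KRT-19-negative nodules, 5629 against 4187 for KRT-19-positive nodules, and 3706 against 1124 between the nodules. For T3 it was 3620 against 1651 after 2 d, 6205 against 3601 after 4 d, 5137 against 2526 for 4 d against 2 d and 4857 against 1821 for 4 d against control. These splits argue against chance as the source of these counts.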
